A study of Homo sapiens with 12 samples.

How the data were processed

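ATAC-seq libraries were made from 12 tumours of the xenograft models HCI-011 and HCI-003, with 3 vehicle and 3 giredestrant libraries per model. The protocol in the labels also describes RNA isolation, which no file analysed here concerns. Per the labels, mice were assigned when tumours measured 450 to 850 mm3, received 80 mg/kg giredestrant or vehicle daily for 5 days, and tumours were collected 4 h after the last dose. Replicates are separate samples by their titles. The sources used here do not say in so many words that each came from its own animal, and p-values measure the spread between these samples.

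The authors deposited 1 peak list per library in the narrowPeak layout, not pooled over replicates. Per the submitters' processing notes, cutadapt 1.9.1, Bowtie2 2.2.6, MACS2 2.1.0 and the build hg38/GRCh38 were used, and the notes as given here assign no roles or settings to them. The deposited fold enrichment (a ratio of the pileup at the summit to the caller's local background, by the authors), the deposited -log10 p and -log10 q, the deposited whole-number display score and, in a last column of another kind, the deposited summit offset in bp are each peak's own values within its list. Values were used here only to order and place peaks within a list, and the display score was not used. From the values, 7 of the 12 lists stop at 300000 peaks and the others near a p of 0.01, and an interval may hold several summits. The deposited lists are named as made without duplicate and mitochondrial reads and with a transposase adjustment, and how mouse reads were handled is not given in the sources used here. A -log10 p grows with sequencing depth, so it was never compared between libraries as accessibility. Read numbers were not used here, so depth is unknown and no counting interval is given.

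On autosomes, peaks of each library were ranked by -log10 p, with ties ordered by fold enrichment and position, and all lists were shortened to the length of the shortest, 262648 summits. Consensus regions of 500 bp were centred on summits from the best rank downwards without overlap, giving 624907. A library's value is the rank score, log2 of 262648 over the rank of its best summit in the region, and 0 where none is listed. Regions ranked within 100000 in at least 3 libraries were tested. There were 125220 of them, and 66881 (53.4%) had a listed summit in all 12 libraries. Because a score stops at 0, changes against a group without listed peaks are bounds.

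Regions were named by the nearest of 19126 autosomal protein-coding gene bodies (a RefSeq gene table of assembly GRCh38.p14) within 100000 bp, which links region and gene by distance only. The analysis as first laid out named the nearest transcription start site. That gene table gives no strand, so gene bodies, and for location either end of a gene within 1000 bp, took its place, and exons and introns were not told apart. No genome sequence was used here, so the planned motif analyses were not run.

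Rank scores were fitted with limma 3.58.1 in R 4.3.3 on 4 group means over all 12 libraries (8 residual degrees of freedom, empirical Bayes with trend and robust settings). The 5 contrasts were giredestrant against vehicle in each model, their mean over both models, their difference (HCI-003 minus HCI-011), and the vehicle groups against each other. Benjamini-Hochberg adjusted p below 0.05 over the tested regions was the threshold. The fit shares its spread across groups, which assumes that they vary alike. Lists of regions nearest to 12 sets of genes were tested with camera (preset correlation 0.01, and an estimated correlation) and with fry. camera compares a list with other regions, whereas fry tests whether its regions move one way. Peak sets were compared by the Jaccard index of covered bases and by location with two-sided exact permutations of treatment within models (400 assignments). Lost and gained regions were those within rank 50000 in all 3 libraries of 1 group and absent in all 3 of the other. The R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

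Grouping, tests, gene lists, the rule for named regions and the alternatives were fixed before the data were examined, apart from those said to be chosen later. The rule named the 10 largest falls and 10 largest rises per treatment contrast, 1 per gene, the 5 largest differences each way for the vehicle and difference contrasts, up to 4 genes of smallest p per list, and GREB1, PGR, TFF1, XBP1, MYC, CCND1, ESR1, FOXA1 and GATA3 throughout. Sex chromosomes were left out, and 1 region that the rule picks is not reported here. The alternatives laid out in advance changed the number of peaks used, the ranking value, the scale, the region filter, the overlap that counts, the moderation, a replicate block, the libraries in the fit, and each library in turn. Chosen after seeing the data were a fit on regions listed in all libraries, covariates for the -log10 p at rank 50000 and at the list end, and the changes forced by the gene table.

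The fit was tested on simulated data of 125220 regions, in which 100 regions were changed by 1 and 100 by 2 rank-score units, up or down, in both models. Of the 2-unit changes, 82% were recovered in both models together, 26% in HCI-011 and 28% in HCI-003, with 1 to 5 false calls. Of the 1-unit changes, 4% were recovered in both models together and 0% in either model alone. Few regions were changed in the simulation, and where more change the Benjamini-Hochberg threshold lets smaller changes pass. The changed regions had a mean vehicle score above 2 in both models. Noise was independent, with 1 spread per region for all groups. Recovery near a score of 0 and groups of unequal spread were therefore not tested.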

Results

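Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 2 patient-derived xenograft models of oestrogen receptor-positive breast cancer, HCI-011 and HCI-003. In such a model, human tumour tissue is grown in immunocompromised mice, which here also received oestrogen. Tumour-bearing mice received vehicle or giredestrant (GDC-9545), an oral compound that blocks the oestrogen receptor and promotes its degradation, at 80 mg/kg once daily for 5 days, and tumours were taken 4 h after the last dose. The 2 models and 2 treatments gave 4 groups of 3 libraries, 12 libraries in all. Each library is represented by its own list of 270371 to 299744 called peak summits on GRCh38. No read numbers were used here, so the depth of each library is unknown and no counting interval can be given. Peaks were therefore compared by their rank within lists shortened to equal length. A rank score of 0 means that no peak was listed, and a change of 1 means a 2-fold better or worse rank. Changes in rank score are given with their standard error (SE) from limma, n = 3 libraries per group, and adjusted p-values are Benjamini-Hochberg values over the 125220 regions tested. A rank is relative: a region can lose rank because others gained, and a change to or from a group without a listed peak is a lower bound on its size.

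The xenograft model was the main difference between libraries and treatment the next. The first principal component of the rank scores held 62.6% of the variance and separated HCI-011, at -319.4 to -168.4, from HCI-003, at 238.6 to 249.8. The second held 11.7% and ordered the treatments in both models: vehicle libraries lay at 127.2 to 166.7 in HCI-011 and -13 to 103.4 in HCI-003, and giredestrant libraries at -132.9 to -93 and -94.6 to -68.7. Across regions, which are not independent replicates, Pearson's r between replicates was 0.90 to 0.95 for HCI-011 vehicle, 0.93 to 0.96 for HCI-011 giredestrant, 0.85 to 0.92 for HCI-003 vehicle and 0.88 to 0.91 for HCI-003 giredestrant. Between treatments r was 0.76 to 0.88 in HCI-011 and 0.84 to 0.90 in HCI-003, so in HCI-003 the treatments differed little more than replicates did. HCI-003 vehicle replicate 1 carries the model name HCI-011 in one of its labels and was grouped by its title. Its r was 0.84 to 0.92 with the other HCI-003 libraries and 0.45 to 0.63 with the HCI-011 libraries.

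**Figure D1:**
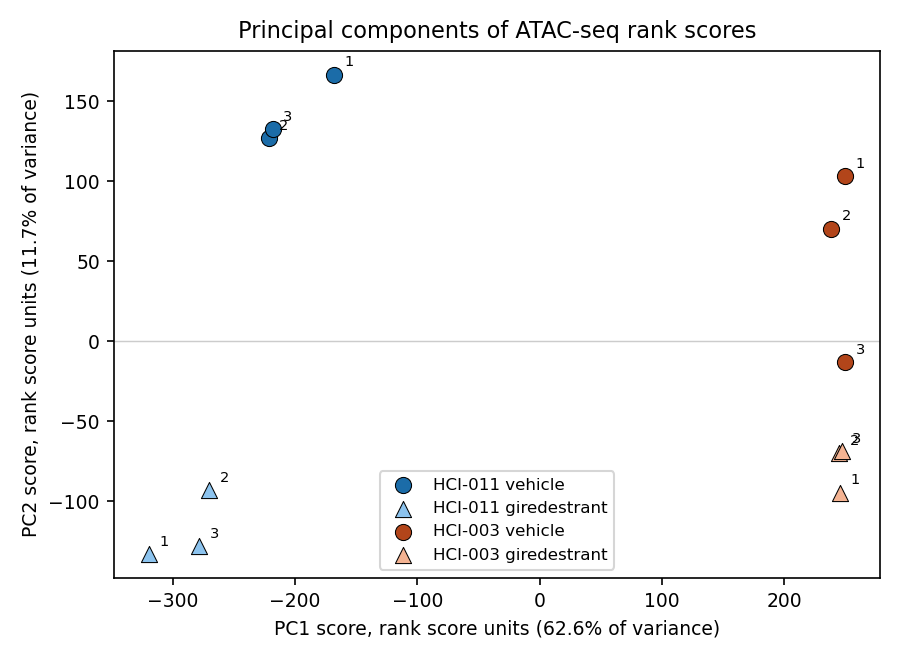
Principal components of the rank scores of 125220 regions, 1 point per library, coloured by group (3 libraries each). The first component (x axis, 62.6% of variance) separates the xenograft models, and on the second (y axis, 11.7%) every giredestrant library lies below the vehicle libraries of its model, with HCI-003 vehicle replicate 3 at -13 nearest to them.

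The first comparison asked what giredestrant changed on average over both models. Some regions near genes that oestrogen induces lost rank, and fewer gained it. A region inside GREB1, an oestrogen-induced regulator of growth (chromosome 2, 11532450 to 11532949), changed by -2.0 (SE 0.21, adjusted p = 2.7e-05), with -1.63 in HCI-011 and -2.36 in HCI-003. A region inside PGR, the progesterone receptor gene (chromosome 11, 101034038 to 101034537), changed by -2.47 (SE 0.25, adjusted p = 1.59e-05), and 1 at 312 bp from TFF1, which encodes a secreted trefoil peptide (chromosome 21, 42366597 to 42367096), by -1.60 (SE 0.22, adjusted p = 0.000216), although in HCI-003 alone it did not pass (-1.23, adjusted p = 0.0523). Regions near PDZK1, a scaffold protein gene (chromosome 1, 145708092 to 145708591), and HSPB8, a small heat shock protein gene (chromosome 12, 119171189 to 119171688), changed by -3.22 (SE 0.31) and -2.49 (SE 0.25). HSPB8 did not pass in HCI-003 alone (-1.37, adjusted p = 0.0609), and its effect differed between the models (2.25, adjusted p = 0.029). All 6 giredestrant libraries ranked each of these 5 regions below every vehicle library of their model. Each was picked as the region of smallest p near its gene in this comparison, so that separation follows in part from the choice and is no separate support.

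Regions near transcription factor genes of the luminal lineage and the cell cycle genes examined with them went both ways. The region of smallest p near GATA3, a luminal transcription factor gene (chromosome 10, 8102947 to 8103446), changed by -1.41 (SE 0.24, adjusted p = 0.00121), lower in 6 of 6 treated libraries, but in HCI-003 alone it did not pass (-0.77, adjusted p = 0.295). A region inside ESR1, which encodes the oestrogen receptor itself (chromosome 6, 152048831 to 152049330), changed by 1.27 (SE 0.23, adjusted p = 0.00167) and was higher in 6 of 6, although 7 of the 55 tested regions nearest ESR1 fell and 1 rose. In HCI-003 alone the rise did not pass (1.19, adjusted p = 0.0737). A region 239 bp from MYC, a growth-promoting transcription factor gene (chromosome 8, 127742940 to 127743439), changed by -1.40 (SE 0.24, adjusted p = 0.0013). That change came from HCI-003, at -2.77 (SE 0.34), because in HCI-011 a single vehicle library listed a peak there. Near CCND1, the cyclin D1 gene and the only gene of the ER-induced list with rising regions alone (chromosome 11, 69616596 to 69617095), a region rose by 1.04 (SE 0.27, adjusted p = 0.0159). It passed in neither model alone (adjusted p = 0.179 and 0.109), and the call was lost on a normal score scale of the ranks (adjusted p = 0.256) and when peaks had to overlap the region by at least 250 bp (adjusted p = 0.0826). Near XBP1, a transcription factor gene of the unfolded protein response (chromosome 22, 28813673 to 28814172), a region changed by -0.69 (SE 0.23, adjusted p = 0.0481), and inside FOXA1, a pioneer factor gene (chromosome 14, 37590461 to 37590960), by 0.74 (SE 0.23, adjusted p = 0.0388) with no listed peak in HCI-003. These calls were lost under 15 of 22 and 13 of 19 alternative settings.

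**Figure D2:**
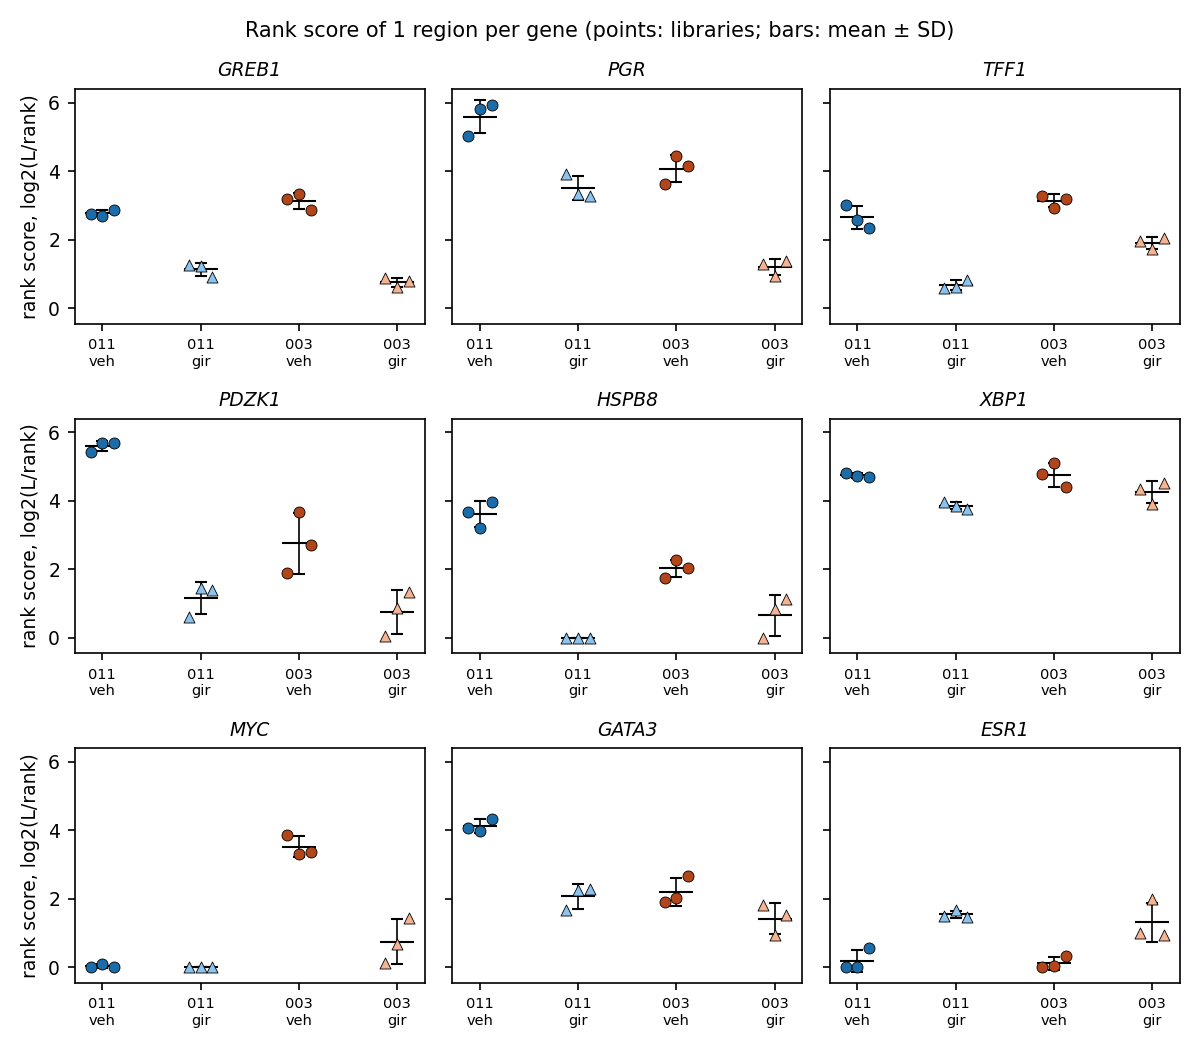
Rank score (y axis, log2 of list length over rank, 0 where no peak is listed) of the region of smallest p near each oestrogen-related gene, per library (points) and group (mean ± SD, n = 3). In GREB1, PGR and TFF1 all 6 giredestrant libraries lie below the vehicle libraries of their model, and at MYC only the HCI-003 libraries carry a consistently listed peak.

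As a group, ER-induced genes lost accessibility rank. Of the 552 tested regions nearest to the 40 ER-induced genes, 101 fell, 25 rose and 426 did not pass the test, and adjusted over the list alone 124 fell and 34 rose. Among the genes, 24 had only falling regions, 1 only rising ones, 13 both and 2 none. GREB1 was 1 of the 13, with 9 falling and 6 rising regions of 35, and MYC another, with 10 and 3 of 32. TPD52L1, PKIB and FHL2 had 8 of 23, 7 of 22 and 5 of 17 regions lower and none higher. The median change over the list was -0.22, against 0.01 over all tested regions, and camera gave an adjusted p of 0.00271, or adjusted p = 0.0449 with an estimated correlation. Members of the list are linked to regions by distance alone.

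None of the other 11 lists passed camera in this comparison, but fry, which asks whether a list's own regions move one way, gave an adjusted p of 0.0149 for hypoxia genes and for growth factor receptor and PI3K genes and of 0.000224 for ER-induced genes. The first 2 lists passed in HCI-011 alone (fry adjusted p = 0.00397 and 0.0424). In HCI-003 alone neither passed (0.778 and 0.184), with a median of 0.02 for hypoxia genes. The mean change of growth factor receptor and PI3K genes was -0.16 in HCI-011 and -0.11 in HCI-003. Whether the lists differed between the models was not tested. A mean over both models can pass through HCI-011 alone. In HCI-003 alone 1.6% of all tested regions passed. Rising and falling there were 0 and 1 regions of ER-repressed, 2 and 2 of luminal and 0 and 1 of basal genes. For cell cycle genes they were 1 and 3, and for growth factor receptor and PI3K genes 1 and 5. No region nearest NDRG1, EGFR, MLPH, CLDN4, CDH1, FN1 or UHRF1 fell there. At least 1 fell nearest GRHL2, MYLK, MYBL2, MKI67, FGFR1, ERBB4, RET and MET. In both models together, 7 of 175 regions of ER-repressed genes rose and 11 fell (list alone, 7 and 10, camera adjusted p = 0.981). The median of that list was 0.07 and its mean -0.02. NDRG1, which is induced by stress and low oxygen, had a region at -2.78, EGFR, a growth factor receptor gene, 1 at -1.72, and PSCA and TGFB2 regions at 1.23 and 1.26. Among luminal breast identity genes 12 of 406 rose and 37 fell (list alone, 11 and 35, adjusted p = 0.503), with falls near MLPH (-2.37), GRHL2 (-2.11), which encodes an epithelial transcription factor, CLDN4 (-1.61) and CDH1 (-1.46), the E-cadherin gene. Among basal and mesenchymal genes 10 of 143 rose and 11 fell (list alone, 10 and 11, adjusted p = 0.941). In that list regions in MYLK (-2.19) and FN1 (-1.79) fell, and regions in the cadherin genes CDH3 (1.07) and CDH2 (0.92) rose. Cell cycle genes were also divided, with 10 of 123 higher and 11 lower (list alone, 11 and 14, adjusted p = 0.941): regions in MYBL2 (-1.67) and UHRF1 (-1.31) and 1 near MKI67 (-2.19) fell and 1 in MCM5 (1.38) rose, although 3 of the 12 regions nearest MKI67 rose and only this 1 fell. Among growth factor receptor and PI3K genes 15 of 294 rose and 31 fell (list alone, 16 and 33, adjusted p = 0.49). The 4 receptor kinase genes named from it by smallest p, FGFR1 (-3.16), ERBB4 (-2.20), RET (-2.08) and MET (-2.05), all had a falling region. RET is also in the ER-induced list. FGFR1 had 9 falling and 2 rising regions of 40, and ERBB4 4 and 1 of 40. FGFR2 and INSR, receptor kinase genes of the same list, had only rising regions, 2 and 3. Among the 17 genes, 4 had only falling regions, 4 only rising ones, 7 both and 2 none.

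Hypoxia genes had 7 of 143 regions higher and 18 lower (list alone, 8 and 19, adjusted p = 0.503), with falls near SLC2A1 (-1.84), the glucose transporter GLUT1 gene, PDK1 (-1.44) and VEGFA (-1.24), although of the 11 regions nearest PDK1 3 fell and 3 rose. The NDRG1 and CLDN4 calls were lost when peaks were ranked by fold enrichment (adjusted p = 0.713 and 0.674). Immediate early genes had 6 of 178 higher and 16 lower (list alone, 6 and 15, adjusted p = 0.715), with falls near EGR2 (-2.54), IER3 (-2.06), FOSL2 (-1.24) and KLF4 (-1.23). Interferon and antigen presentation genes had 2 of 54 higher and 3 lower (list alone, 1 and 0, adjusted p = 0.941). Regions in OAS1 (1.41) and near IRF1 (1.22) rose, 1 near B2M (-0.91) fell, and of the 14 regions nearest IRF1 2 fell and 1 rose. The calls near B2M and IRF1 were lost under 11 of 19 and 8 of 22 alternatives, most of them the loss of 1 library, and IRF9 stood at -0.70 (adjusted p = 0.0514). Regions near human marker genes of other cell types gave the same mixed result. Peaks lie on the human genome and the handling of mouse reads is not given. These lists therefore do not measure cells of the mouse host in the tumours. Leukocyte markers had 3 of 43 higher and 4 lower (list alone, 3 and 5, adjusted p = 0.941), with CD2 at 1.22 and SPI1, ITGAM and CD68 at -1.10, -0.89 and -0.85, and the call near CD68 was lost under 10 of 21 alternatives, 8 of them the loss of 1 library. Endothelial markers had 9 of 88 higher and 7 lower (list alone, 9 and 7, adjusted p = 0.819), with PECAM1 (-1.73) and VWF (-1.47) lower and CDH5 (1.60) and KDR (1.02) higher, although of the 18 regions nearest VWF 3 rose and 2 fell. Fibroblast markers had 6 of 82 higher and 7 lower (list alone, 10 and 9, adjusted p = 0.941), with COL5A1 (1.26) higher and COL1A1 (-1.41), FBLN1 (-1.12) and POSTN (-0.98) lower, although of the 18 regions nearest FBLN1 2 rose and 1 fell. On a normal score scale the calls near CDH2, KLF4, IRF1, CD2, KDR, COL1A1 and FBLN1 were lost (adjusted p = 0.431, 0.0611, 0.0913, 0.068, 0.064, 0.127 and 0.117). With an overlap of at least 250 bp required, the calls near IRF1, B2M, SPI1, CD2, CD68, COL1A1 and POSTN were lost. KLF4, ITGAM, TGFB2 and HSPB8 each had 1 falling and 1 rising region, PSCA 1 and 2, RET 2 and 1, and COL5A1 1 and 4. In HCI-003 alone, rising and falling regions were 0 and 2 for hypoxia and for immediate early genes and 0 and 1 for interferon genes. They were 0 and 0 for leukocyte, 2 and 0 for endothelial and 0 and 1 for fibroblast markers. No region nearest SLC2A1, PDK1, IER3, PECAM1 or VWF fell there, whereas 1 nearest each of VEGFA, EGR2 and FOSL2 did. At the KDR region no HCI-003 library listed a peak.

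**Figure D3:**
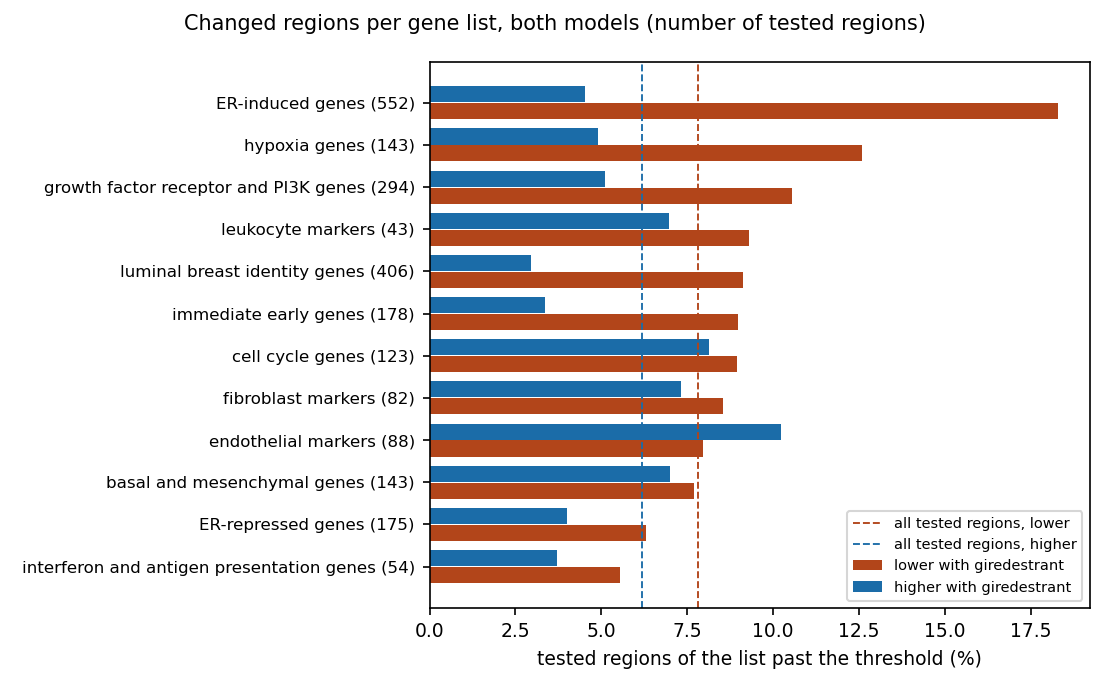
Percent of the tested regions of each gene list that rose or fell with giredestrant in both models together, with the number of tested regions per list and the percent over all tested regions for comparison. ER-induced genes have 18.3% lower and 4.5% higher regions, against 7.8% and 6.2% over all tested regions.

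The largest falls shared by both models lay near genes outside those lists. A region inside RALGAPA2, which encodes a regulator of Ral GTPases (chromosome 20, 20441228 to 20441727), changed by -4.11 (SE 0.35), 1 at 3227 bp from TRH, the thyrotropin-releasing hormone gene (chromosome 3, 129971243 to 129971742), by -4.06 (SE 0.28), and 1 inside CPQ, which encodes a carboxypeptidase (chromosome 8, 96945719 to 96946218), by -4.03 (SE 0.28). Regions near MYOG, a muscle transcription factor gene (-4.01), in PLCD3, a phospholipase C gene (-3.98), in TGIF2, a homeobox repressor gene (-3.94), and near RBBP8, a DNA end resection gene (-3.87), followed. DHRS2 (-3.69) and TRPC6 (-3.61), the latter a cation channel gene, had the other large falls, with PPIAL4H (-3.87), a member of a family of near-identical copies at which peak positions are uncertain. The largest rises were smaller. They lay in RAB6A, which encodes a Golgi GTPase (chromosome 11, 73743456 to 73743955, 2.91, SE 0.36), near GALNT2, a glycosylation enzyme gene (2.72, SE 0.31), in FSTL4 (2.61), and near CD177 (2.53), SORCS2 (2.51) and CCDC190 (2.51). TRIQK (2.46), CARS2 (2.42), EPN2 (2.40) and GPRIN2 (2.72) completed the named rises, and GPRIN2 also has near-identical copies. In HCI-003 alone GPRIN2 (0.57, adjusted p = 0.537), EPN2 (0.54, adjusted p = 0.546) and SORCS2 (1.58, adjusted p = 0.16) did not pass, and the effect at GPRIN2 and EPN2 differed between the models (adjusted p = 0.00348 and 0.00458).

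In total limma called 17555 of the 125220 regions changed in the mean of the 2 model effects (14%), 7758 higher and 9797 lower. A large change in 1 model can pass this test. Called in each model separately, in the same direction, were 703 lower and 162 higher regions. Changed regions lay away from gene ends: 5.2% of the lower and 4.6% of the higher regions were within 1000 bp of either end of a protein-coding gene, against 16.1% of regions not called. The counts depend on the processing and on single libraries. They were 3197 higher and 6068 lower on a normal score scale, 3274 and 5155 among regions listed in all libraries, 4909 higher with a filter at rank 50000, and 5119 higher without HCI-011 giredestrant replicate 1.

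**Figure D4:**
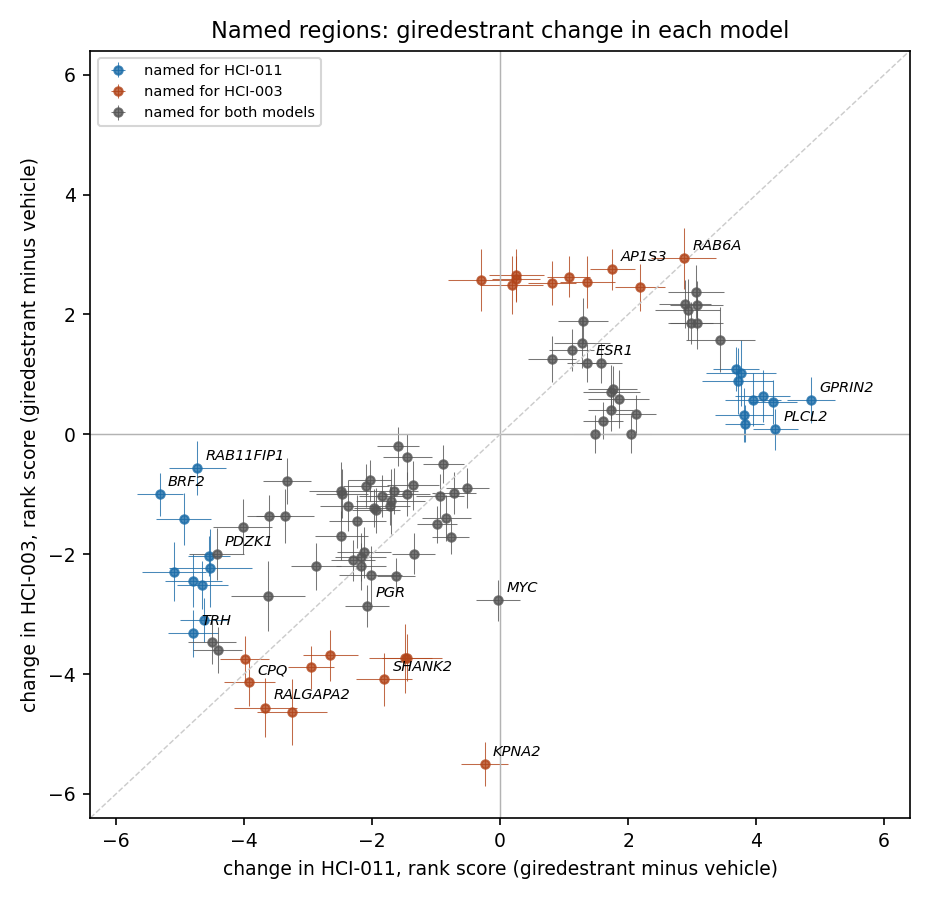
Change in rank score with giredestrant of each named region in HCI-011 (x axis) and HCI-003 (y axis), with bars of 1 SE. Regions such as CPQ (-3.92 and -4.14) changed alike in the models, whereas BRF2 (-5.32 and -1.0), GPRIN2 (4.86 and 0.57) and KPNA2 (-0.24 and -5.50) changed mainly in 1 model.

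Within HCI-011, the largest fall was at a region 3450 bp from BRF2, which encodes a subunit of an RNA polymerase III initiation factor (chromosome 8, 37853061 to 37853560), at -5.32 (SE 0.36, adjusted p = 2.42e-06). It was followed by DHRS2 (-5.10, SE 0.50), a dehydrogenase gene, RIMS4 (-4.94, SE 0.43), TRH (-4.80, SE 0.39), TRPC6 (-4.79) and RAB11FIP1 (-4.73), an endosome recycling gene. Regions near ZPLD1 (-4.65), PPIAL4H (-4.63), HNRNPLL (-4.55) and IL24 (-4.53), a cytokine gene, completed the largest falls. The largest rises were near GPRIN2 (4.86, SE 0.38), in PLCL2 (4.30, SE 0.35), in EPN2 (4.27, SE 0.37), an endocytosis gene, and in POLR3C (4.10, SE 0.43), an RNA polymerase III subunit gene. ANKEF1 (3.95), PTPRT (3.82), a receptor phosphatase gene, ICE2 (3.81), TRAPPC9 (3.76), XCL1 (3.71), a chemokine gene, and PMEPA1 (3.69), which encodes an inhibitor of TGF-beta signalling, followed. ER-induced genes fell as a group, with 75 regions lower and 25 higher (list alone, 86 and 29) and a camera adjusted p of 0.0249, or adjusted p = 0.117 with an estimated correlation. No other list passed camera in HCI-011.

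In HCI-011, 9268 regions rose and 8716 fell, 14.4% of those tested. The share of lower regions was 48.5%, but 63.4% on a normal score scale (3368 higher, 5831 lower) and 61.0% among regions listed in all 12 libraries (3203 and 5000). It was 44.3% with ranking by fold enrichment and 39.4% (13855 and 9003) when regions listed in at least 3 libraries were tested, so which direction prevails depends on the processing. With a filter at rank 50000, 5525 rose. Without vehicle replicate 1 the counts were 5448 and 5742, without giredestrant replicate 1 they were 5097 and 4957, and without giredestrant replicate 3 4948 fell. When peaks were ranked by fold enrichment, the calls at TRPC6, RAB11FIP1, EPN2, POLR3C and XCL1 were lost.

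Within HCI-003 the falls again included TGIF2 (-4.63, SE 0.55), RALGAPA2 (-4.56, SE 0.49), CPQ (-4.14, SE 0.40) and RBBP8 (-3.75, SE 0.38). Others lay in SHANK2 (-4.09), a synaptic scaffold gene, and near CCSAP (-3.89), POFUT3 (-3.74), TUBG1 (-3.73), the gamma-tubulin gene, and CAMK1G (-3.69). The largest value, -5.50 (SE 0.37), belonged to a region inside KPNA2, an importin gene (chromosome 17, 68035655 to 68036154), where no treated library listed a summit. It was 2.22 with an adjusted p of 0.699 when a peak counted by an overlap of at least 250 bp in place of its summit, so that this change rests on where the summit was placed. Rises were near or in RAB6A (2.94, SE 0.51), AP1S3 (2.75), TNS3 (2.66), which encodes a focal adhesion protein, RNF144B (2.63), SRCIN1 (2.59), CERS1 (2.58), a ceramide synthase gene, UTP20 (2.54), INTS4 (2.52), OSTCP2 (2.49) and PATJ (2.45), a cell polarity gene. The call at CERS1 was lost under 8 alternatives and that at OSTCP2 under 5. With ranking by fold enrichment the calls at POFUT3, SRCIN1 and RALGAPA2 were lost (adjusted p = 0.226, 0.159 and 0.0586), on a normal score scale those at TNS3, RNF144B and PATJ (0.174, 0.137 and 0.0808), and without vehicle replicate 2 that at RAB6A (2.52, adjusted p = 0.0502). Among ER-induced genes 27 regions fell and 3 rose (list alone, 58 and 8), with a camera adjusted p of 0.0157, or adjusted p = 0.0943 with an estimated correlation. No other list passed camera in HCI-003.

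In HCI-003, 590 regions rose and 1447 fell, 1.6% of those tested. A limma fit of the 6 HCI-003 libraries alone called 0 regions in either direction, with 5339 higher and 7439 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.157. In the fit of all 12 libraries the counts at that unadjusted p were 7467 and 11054. A fit of the 6 HCI-011 libraries alone called 8863 regions higher and 9553 lower in that model. The counts rested on the processing and on single libraries. They were 211 and 529 with a covariate for library quality, 220 and 454 among regions listed in all libraries, 329 and 933 with ranking by fold enrichment, 353 and 936 with a filter at rank 50000, and 350 higher on a normal score scale. They were 1441 higher and 3434 lower without vehicle replicate 3, 189 and 443 without vehicle replicate 2, 144 and 470 without vehicle replicate 1, and 358 higher without giredestrant replicate 2. Leaving out an HCI-011 library, which enters through the shared spread, gave 391 higher without vehicle replicate 2, 353 without vehicle replicate 3, 390 without giredestrant replicate 1, 334 higher and 912 lower without giredestrant replicate 2, and 343 and 907 without giredestrant replicate 3.

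The effect itself differed between the models at 2187 regions. Taken as HCI-003 minus HCI-011, it was higher at 630 regions and lower at 1557. Regions near BRF2 (4.33, SE 0.51, adjusted p = 0.00296), in ADAM29 (4.26, SE 0.46), in RAB11FIP1 (4.16), in PCDHA1 (3.84) and near APLP2 (3.80), an amyloid precursor-like gene, fell in HCI-011 but did not pass in HCI-003. In ADAM29 no HCI-003 library listed a peak, and near BRF2 the mean vehicle score in HCI-003 was only 1.0 and no treated library listed a peak. At these regions HCI-003 could fall no further, so the size of the difference is set by the floor of the score. Regions near GPRIN2 (-4.28, SE 0.54), in PLCL2 (-4.22, SE 0.49) and in MYCBP2 (-4.11) rose in HCI-011 only, and KPNA2 (-5.26, SE 0.52) fell in HCI-003 only. In PLCL2 and MYCBP2 a single HCI-003 library listed a peak (scores 0.23 and 1.40), so a change there below the end of the lists would not be seen. The call of the difference was lost on a normal score scale for BRF2, PLCL2 and MYCBP2 (adjusted p = 0.341, 0.29 and 0.21) and with ranking by fold enrichment for RAB11FIP1 (0.721) and APLP2 (0.103). For PCDHA1 it was lost under 5 alternatives, among them the fit without HCI-003 vehicle replicate 2 (adjusted p = 0.051). At KPNA2 the overlap rule turned it to 4.01 (adjusted p = 0.503). At MYC the difference was -2.73 (SE 0.49, adjusted p = 0.013). There a single HCI-011 vehicle library listed a peak, at a score of 0.1, so HCI-011 had almost no room to fall and the floor sets this size too. The lower share was 71.2%, against 60.3% on a normal score scale (332 higher, 505 lower) and 43.5% among regions listed in all 12 libraries (218 and 168). Other settings also moved the counts by over 1.5 times: 134 and 270 with a covariate for library quality, 112 and 324 when regions listed in at least 3 libraries were tested, 909 lower with a filter at rank 50000, 1297 and 2887 with the best 150000 peaks and 947 and 2638 with an overlap of at least 250 bp. Each left-out library except HCI-011 vehicle replicate 2 and giredestrant replicate 2 and HCI-003 vehicle replicate 3 and giredestrant replicate 1 moved a count by over 1.5 times. The counts, higher and lower, were 395 and 954 without HCI-011 vehicle replicate 1, 345 higher without vehicle replicate 3, 228 and 773 without giredestrant replicate 1, and 233 and 979 without giredestrant replicate 3. They were 358 and 727 without HCI-003 vehicle replicate 1, 152 and 279 without vehicle replicate 2, 264 and 692 without giredestrant replicate 2, and 332 and 838 without giredestrant replicate 3.

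Regions that fell were shared between the models beyond independence. Of the 8716 regions lower in HCI-011 and the 1447 lower in HCI-003, 703 were the same regions, against 100.7 for independent calls, and 162 of the rising regions were shared against 43.7. The models share no control libraries, but both sets of calls use 1 spread per region from the same fit. A region of small spread thus passes more easily in both models, which the expected numbers leave out. In opposite directions, 1 region fell in HCI-011 and rose in HCI-003, and 8 did the reverse. At the regions that fell in HCI-011 the median change was -1.55 there and -0.53 in HCI-003, where 84.4% of those with any change had the same sign and 360 had no change. At those that rose the medians were 1.49 and 0.07, with 70.1% of those with any change of the same sign and 2114 without change, and 22.8% had no listed peak in any HCI-003 library, against 4.1% of those that fell. Among regions listed in all 12 libraries, the medians in HCI-003 were -0.52 and 0.35. Across all tested regions, which are not independent replicates, Pearson's r of the changes in the models was 0.35 and Spearman's rho 0.30.

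Vehicle tumours of the models differed at 56847 regions (45.4%), 27460 higher and 29387 lower in HCI-003. With fewer regions tested the counts were 15547 and 17731 (filter at rank 50000) and 10359 and 10798 (listed in all libraries). Higher in HCI-003 were regions in CSMD3 (8.79, SE 0.57) and BRI3BP (8.40, SE 0.33) and near RPS6KA4 (8.61, SE 0.48), a kinase gene, PLEKHO1 (8.33, SE 0.35) and ID2 (8.29, SE 0.31), an inhibitor of helix-loop-helix transcription factors. Lower in HCI-003 were regions in BAG4 (-9.33, SE 0.55), SPECC1 (-8.47, SE 0.39), RBBP6 (-8.41, SE 0.38) and MTA1 (-8.17, SE 0.40), a chromatin remodelling gene, and near RAB11FIP1 (-8.04, SE 0.60). The HCI-011 vehicle libraries listed no peak in the CSMD3 and ID2 regions. When peaks were ranked by fold enrichment, the RAB11FIP1 difference was 0.23 (adjusted p = 0.693) and that at SPECC1 was -0.72 (adjusted p = 0.411). Each model comes from 1 donor, so model, donor and copy number cannot be told apart in this comparison.

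Complete loss or gain of a strong peak was rare. In HCI-011, 17 regions ranked within the best 50000 in all vehicle libraries and absent from all giredestrant lists were lost, and 13 were gained. The lost regions included those near HSPB8, HEATR3 and NUP133 and in ANKFN1 and SEPTIN9, and the gained ones those in OSBPL6, KCTD10, MYO1H and HMGA2, an architectural chromatin protein gene, all chosen after their values were seen. In HCI-003, 5 were lost, among them regions in KPNA2, SPOCK1 and SEC61A2, and 0 were gained. The loss in KPNA2 rests on where summits were placed, since by an overlap of at least 250 bp the region changed by 2.22 (adjusted p = 0.699). This is a count of listed peaks without a test, and no unadjusted p belongs to it. A single region, on chromosome 10 from 44641983 to 44642482 and 257136 bp from the nearest protein-coding gene, was lost in both models. These counts depend on the definition and on single libraries: within the best 100000, 190 were lost and 333 gained in HCI-011 and 112 and 20 in HCI-003. Leaving out a library asks for fewer libraries and so raises the counts. In HCI-011, 33 were lost without vehicle replicate 1, 35 gained without vehicle replicate 2, 25 gained without vehicle replicate 3, 60 lost and 29 gained without giredestrant replicate 2, and 24 gained without giredestrant replicate 3. In HCI-003, 22 were lost and 2 gained without vehicle replicate 3, 13 and 1 without giredestrant replicate 1, 10 and 2 without giredestrant replicate 2, and 18 and 3 without giredestrant replicate 3, and 1 was gained without vehicle replicate 2.

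Peak sets were more alike within than between treatments. The mean Jaccard index of the bases covered by the best 50000 peaks was 0.655 within HCI-011 vehicle, 0.664 within HCI-011 giredestrant and 0.565 between these treatments. In HCI-003 it was 0.584, 0.609 and 0.578, and between models 0.427. The difference within minus between treatments was 0.056 over both models (two-sided exact permutation p = 0.03, 400 assignments). In HCI-011 it was 0.094 (exact p = 0.1) and in HCI-003 0.018 (exact p = 0.4), and 3 libraries against 3 cannot give a p below 0.1. The share of the best 50000 summits within 1000 bp of a gene end was 22.6% ± 1.88 (SD, n = 3) in HCI-011 vehicle, 21.33% ± 2.14 in HCI-011 giredestrant, 24.2% ± 3.09 in HCI-003 vehicle and 25.52% ± 0.4 in HCI-003 giredestrant. The treatments differed by 0.03 points (two-sided exact permutation p = 0.985).

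Of 6 measures of the lists themselves, 1 passed the test between treatments. The -log10 p of the last listed peak was 2.82 ± 1.06 and 3.57 ± 0.213 (SD, n = 3) in HCI-011 and HCI-003 vehicle, and 2.0 ± 0.000306 and 2.43 ± 0.709 with giredestrant. The difference was -0.981 (two-sided exact permutation p = 0.005, adjusted p = 0.03 over 6 measures). HCI-011 vehicle replicate 1 ended at 2.00077 and the HCI-011 giredestrant lists at 2.00056, 2.00003 and 2.00056. All of these end near a p of 0.01, so their order means little, and with them tied the p would be larger. The counts of changed regions were not fitted with this measure as a covariate, so its effect on them was not tested. The number of summits (exact p = 0.465), of summits with q at or below 0.01 (0.205), the covered length (0.41), the median width (0.685) and the -log10 p at rank 50000 (0.65) gave no such difference.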

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

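The tests of the 3 patterns weighed here were chosen only after each pattern was seen, whereas the regrouping of libraries was planned.

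A test of the difference between the giredestrant effects in the 2 models picked out 630 regions with a higher and 1557 with a lower effect in HCI-003 than in HCI-011. The same test picked out the following regions, given as the HCI-003 minus the HCI-011 effect. Those below 0 were KPNA2 (-5.26), GPRIN2 (-4.28), PLCL2 (-4.22), MYCBP2 (-4.11), EPN2 (-3.73), PTPRT (-3.64), ICE2 (-3.49), POLR3C (-3.46), ANKEF1 (-3.37), MYC (-2.73), PMEPA1 (-2.60), TUBG1 (-2.26) and KDR (-2.04). Those above 0 were HSPB8 (2.25), SRCIN1 (2.34), HNRNPLL (2.52), IER3 (2.55), RIMS4 (3.54), APLP2 (3.80), PCDHA1 (3.84), RAB11FIP1 (4.16), ADAM29 (4.26) and BRF2 (4.33). At KDR and ADAM29 no HCI-003 library listed a peak. At PLCL2, PTPRT and MYCBP2 a single HCI-003 library listed one, at scores of 0.23, 0.53 and 1.40. A change of HCI-003 below the end of the lists would not be seen at these regions. Near MYC a single HCI-011 vehicle library listed a peak, at a score of 0.1, so HCI-011 had almost no room to fall. Near BRF2, HNRNPLL and IER3 no treated HCI-003 library listed a peak, so HCI-003 fell as far as the score allows from vehicle means of 1.0, 2.03 and 0.78.

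Regrouping the libraries tested whether any grouping gives as many calls. For HCI-011, HCI-003 and the vehicle groups, the real grouping was the only 1 of 10 with as many changed regions, with at most 0, 258 and 2 in the others, and 10 groupings are too few to exclude chance. For both models together it was the only 1 of 100, with at most 12104 in another, and the ER-induced list gave the smallest camera p in 1 of 100 groupings (-log10 p of 3.65, next 3.29). For the difference between models 6 of 100 groupings gave as many, up to 17555, so this test does not exclude chance. Exchanging the treatment names in 1 model turns the difference into a sum, and among the 85 groupings that mix treatments the highest count was 1. Lost and gained regions were most numerous in 1 of 10 groupings in each model, with at most 1 in any other.

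HCI-003 had 2037 changed regions and HCI-011 had 17984. A larger spread between HCI-003 replicates is excluded as the whole cause: with replicate noise taken out, the SD of the changes in HCI-003 was 0.49 of that in HCI-011 (0.36 against 0.73), and ranged from 0.29 without HCI-003 vehicle replicate 2 to 0.72 without vehicle replicate 3. HCI-003 vehicle replicate 3 is excluded as the whole cause, because 4875 regions changed without it, against at least 10054 in HCI-011 without any 1 of its libraries. Library quality may contribute: with the -log10 p at rank 50000 as a covariate (the list end was not fitted for this count), 404 differences between models were called, 383 of them among the 2187 called without it, and a term that costs a degree of freedom also removes calls, so this stays open. A weaker response of HCI-003 tumours is the biological alternative, and with 1 donor per model it cannot be generalised.

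HCI-003 vehicle replicate 3 lay toward the treated libraries. Its response score, the mean score of regions lower in HCI-011 minus that of regions higher there, was 1.20, against 1.85 and 1.70 in the other vehicle libraries. An exchange with a treated library is excluded, because the highest treated score was 0.79. Its own 1.20 lay above a treated mean of 0.73 (SD 0.09, n = 3) but also below both other vehicle libraries. A spread from 3 libraries is poorly known, so a giredestrant tumour named vehicle stays open. On 1 of the 6 quality measures counted it lay beyond both other vehicle libraries on the side of the treated mean. Measures outside those 6 went both ways. Its share of the best 50000 summits near gene ends was 27.61%, against 21.59% and 23.39% in the other vehicle libraries. In the treated ones that share was 25.12% to 25.93%. Its median fold enrichment was 3.60, against 4.00 and 4.38 in the other vehicle libraries and 3.41 to 3.73 in the treated ones. Its fold enrichment at rank 50000 was 9.03, above the 8.23 and 7.90 of the other vehicle libraries. Quality like that of the treated libraries therefore stays open, and variation between tumours was not tested.

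Falls were shared between the models more than rises. At regions called in a fit of the HCI-011 libraries alone, 9553 lower and 8863 higher, the median HCI-003 change was -0.54 and 0.13. Peaks missing from HCI-003 lists account for part of this: among regions listed in all libraries the medians were -0.51 and 0.34, a size ratio of 0.68 (0.53 to 0.82 without any 1 HCI-003 library), which excludes them as the whole cause. With the -log10 p at rank 50000 as a covariate the ratio was 0.71, but that fit was not repeated without single libraries. With the -log10 p at the list end it was 0.69, and 1.01 without HCI-003 giredestrant replicate 3. Library quality therefore stays open by both measures. A difference in biology between the models was not tested.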

How the results depend on the processing

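Of 2904 comparisons of a named region with an alternative, 2757 kept direction and call, 141 lost the call, 3 gained it and 3 reversed. For both models together, the ER-induced list passed in the 18 of 18 alternatives run for it (adjusted p 0.000224 to 0.0449). Most of these left out a single library. The list was not tested with ranking by fold enrichment, a normal score scale, the stricter overlap, regions listed in all libraries or a quality covariate. In each model alone it did not pass with an estimated correlation (camera adjusted p = 0.117 in HCI-011 and 0.0943 in HCI-003). Depth is unknown, so its limits cannot be given. Counts below are higher then lower, and the cause was not tested unless stated. The planned motif shares and motif region sets were not run.

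With the best 150000 peaks, the difference between models gave 1297 and 2887. Ranking by fold enrichment gave 329 and 933 in HCI-003, 51 gained in HCI-011, 11 lost in HCI-003, and reversed the vehicle difference near RAB11FIP1 (0.23). A normal score gave 3368 higher in HCI-011, 350 higher in HCI-003, 3197 and 6068 in both models and 332 and 505 for the difference. A filter at rank 50000 tests fewer regions (66932) and gave 5525 higher in HCI-011, 353 and 936 in HCI-003, 4909 higher in both models, 909 lower for the difference, 15547 and 17731 between vehicle groups, and turned the direction of the cell cycle and leukocyte lists (adjusted p = 0.974 each). Testing 294846 regions listed in 3 libraries gave 112 and 324 for the difference. An overlap of at least 250 bp gave 947 and 2638 for the difference and reversed KPNA2 in HCI-003 (2.22) and in the difference (4.01). The HCI-003 libraries alone gave 0 and 0. The HCI-011 libraries alone, also 6, gave 8863 and 9553. Changes were larger there (SD 0.73 against 0.36 in HCI-003, replicate noise taken out), so this does not tell whether fewer samples emptied the HCI-003 fit. In the fit of all 12 libraries HCI-003 shares a spread with HCI-011, although the error SD of its changes was larger (0.47 against 0.36).

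Chosen after the data were seen, regions listed in all libraries (66881, fewer tested) gave 3203 and 5000 in HCI-011, 220 and 454 in HCI-003, 3274 and 5155 in both models, 218 and 168 for the difference and 10359 and 10798 between vehicle groups. The quality covariate gave 211 and 529 in HCI-003 and 134 and 270 for the difference. fry gave adjusted p = 0.0149 for the growth factor receptor and hypoxia lists and 0.888, reversed in direction, for ER-repressed genes. Genes within 20000 bp turned the leukocyte list (adjusted p = 0.739). The share near gene ends differed by -0.15 points in the best 100000 peaks, -0.33 in all and -0.08 with 5000 bp. With absence required only beyond rank 150000, more was lost and gained by construction: 91 and 72 in HCI-011, 20 and 1 in HCI-003. Strong peaks within 100000 gave 190 and 333, and 112 and 20. Within 30000 they gave 3 and 0 in HCI-011 and 2 lost in HCI-003.

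Replicate numbers do not pair the samples: residuals of equal numbers correlated at -0.25, -0.17 and -0.10 in HCI-011 and 0.12, 0.09 and 0.04 in HCI-003. With the number as a block, HCI-003 gave 199 and 677, the difference 21 and 57, and the Jaccard difference was 0.056 (exact p = 0.0625 over 64 sign patterns).

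Without any 1 library, counts were 5097 to 10146 and 4948 to 9857 in HCI-011, 144 to 1441 and 443 to 3434 in HCI-003, 5119 to 8673 and 6636 to 12023 in both models, 152 to 560 and 279 to 1592 for the difference, and 22729 to 28913 and 23831 to 30625 between vehicle groups. Adjusted p was 0.0019 to 0.0057 for ER-induced genes, 0.729 to 0.989 for the ER-repressed, basal, cell cycle, leukocyte and fibroblast lists, 0.623 to 0.989 for endothelial, 0.729 to 1 for interferon, 0.34 to 0.593 for growth factor receptor, 0.48 to 0.771 for hypoxia, 0.48 to 0.959 for immediate early and 0.34 to 0.693 for luminal genes. The location difference was -0.62 to 0.88 points, the Jaccard difference 0.05 to 0.071, HCI-011 lost 22 to 60 and gained 15 to 35, and HCI-003 lost 7 to 22 and gained 0 to 3. With 2 libraries left in a group, its spread is taken from all groups.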

Other observations

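The genes below were chosen after their values were seen, and their tests followed the result. Some genes had more changed regions nearby than the 7.7% lower and 5.8% higher among regions with an assigned gene would give. Of the genes tested, 3 had more lower and 1 more higher regions than that. TPRG1 had 13 of 41 regions lower (hypergeometric test over 16914 genes, adjusted p = 0.0404) and KCNH1, a potassium channel gene, 12 of 34 (adjusted p = 0.0385), and an uncharacterised gene had 6 of 7 (adjusted p = 0.0225), with no region of these 3 genes higher. TRAPPC9, which encodes a subunit of a trafficking complex, went the other way, with 21 of 90 regions higher and 5 lower (adjusted p = 0.000583). Neighbouring regions are not independent, so these p-values are too small.

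Few genes had several regions called lower in each model separately. GREB1 had 5 such regions, and 2 higher in each model, and NAV2, a gene of axon guidance, had 4. In both models together GREB1 had 9 of 35 regions lower and NAV2 12 of 59, and neither passed the test for more than chance (adjusted p = 0.646 and 0.778).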
